A study of Homo sapiens with 6 samples.

How the data were processed

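Messenger RNA of H9 human embryonic stem cells was sequenced from polyadenylated RNA on a NovaSeq, per the labels' protocols, and 6 samples in 3 groups of 2 were analysed. The protocols call the replicates of each cell type independent biological replicates. The libraries of dox and no dox cells come from 1 deposited table and the libraries labelled knockout from another. Per the submitters' processing notes the tools were TopHat, HOMER and DESeq2, without versions, and the genome build was hg38. Which tool did which step, and whether counting used strand, is not given in the sources used here. The deposited values are estimated counts per gene, not normalized, and all are multiples of 0.5. The design written before the data were examined had assumed whole counts, so values were rounded to whole numbers, with values midway between whole numbers going to the even one, and the planned test was kept. Both tables hold 1 row per gene symbol, and 27945 rows are in both, with 90 more in the dox table. The knockout table also holds 4 columns of other samples, which were not used.

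The protocol text describes retinoic acid and BMP4 for differentiation in general, whereas the treatment labels give it for the knockout samples alone and list dox or no treatment for the others. The medium of the dox cultures is therefore not known here. Columns of the libraries labelled knockout carry the letters A and B, which were not matched to replicate numbers.

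Groups, comparisons, tests, 18 gene lists, alternatives and the rule for named genes were fixed before the data were examined. The main test was edgeR (4.0.16) in R (4.3.3), with TMM factors, filterByExpr (minimum count 10, minimum total 15), robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. Dox was tested against no dox on those 4 libraries. Both comparisons of the libraries labelled knockout came from 1 model of all 6 libraries. CPM values are the deposited counts of a library scaled to a total of 1000000, computed here. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over the 17 lists that had members in the tables. Lists cover epithelial junctions, epithelial regulators, surface ectoderm, keratinocytes, pluripotency, neural ectoderm, mesenchymal genes, neural crest, mesoderm, endoderm, amnion and trophoblast, retinoic acid response, BMP response, craniofacial development, the integrated stress response, mitochondrially encoded genes, proliferation and the p53 response.

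The rule named GRHL2, then genes with adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups. Of these it took the 6 largest rises and 6 largest falls for dox, and 5 of each for the libraries labelled knockout against no dox. From each list it took the 2 called members with the smallest adjusted p, or 4 for junctions, regulators and surface ectoderm in the dox comparison. A gene could be given its value in another comparison, and genes outside the rule are named as such. Some genes that the rule takes are not reported here. Coordinates are from GENCODE release 29 (GRCh38, the hg38 assembly), in which 25762 rows were found by symbol. A gene at 0 in a whole group has its fold given as a bound against 3 counts over the group. With 1 to 3 counts in a group only levels are given, and such bounds cover counting error only. At the depths in these libraries 1 count is worth 0.0237 to 0.0401 CPM.

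Code was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed. The number of draws was raised to 5 after a single draw had been seen. For dox against no dox (17634 genes) the test recovered 44.5%, 86.9% and 96.1% of genes changed by 0.5, 1 and 2 on the log2 scale, and 17.2% of its calls were genes simulated as unchanged. For the libraries labelled knockout against no dox (17746 genes) the shares were 53.4%, 85.4% and 91.8%, with 11.7% false calls, and against dox (17829 genes) 51.3%, 80.6% and 89.1%, with 11.2%. These shares of false calls exceed the threshold of 0.05 in simulations with 200 changed genes. The real comparisons called far more genes, and such a share depends on how many genes change. The shares therefore cannot be carried over to the counts of changed genes given here. How many of those calls are false was not measured. A simulated changed list was called by camera with the preset correlation in all 3 comparisons and with the estimated correlation in 2 of them, the dox comparison being the exception.

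Alternatives were other scalings (relative log expression, library size alone), DESeq2 (1.42.0), limma voom, other filters, a 2-fold minimum, the replicate number as a block, other sets of libraries in the model and each library left out in turn. A group left with a lone library was assumed to vary like the other groups of the fit. Further ones were added after seeing the data: protein-coding genes alone, libraries thinned to the smallest, omission of genes that are pseudoautosomal or have identical copies, and midway values rounded down. Python (3.11.15) with matplotlib (3.10.9) drew the plots.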

Results

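The series measured messenger RNA in H9 cells, an established human embryonic stem cell line, in which the epithelial transcription factor GRHL2 had been either induced or targeted for knockout. The 6 libraries form 3 groups of 2 and were collected at day 7. Cells carrying a doxycycline-inducible GRHL2 were given doxycycline (dox) or left untreated (no dox). Cells labelled as GRHL2 knockout were given 1 µM retinoic acid and 5 ng/mL BMP4, a pair of signals that drives pluripotent cells towards surface ectoderm. The no dox libraries held 34849304.5 and 42243075 counts, the dox libraries 36495071.5 and 35714641.5, and the libraries labelled knockout 26425845.5 and 24946912. Across genes, log2 CPM (counts scaled to a library total of 1000000) of replicates correlated at 0.998 in no dox, 0.994 in dox and 0.998 in the libraries labelled knockout, although genes are not independent replicates. The replicates of every group differed by more than sampling noise, with a chi-square per degree of freedom of 5.26, 15.0 and 2.92 in the same order. This value grows with depth, and with all libraries thinned to the smallest it was 3.90, 10.9 and 2.86.

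GRHL2 (chromosome 8, 101492432 to 101669726, hg38) stood at 24.8 ± 2.37 CPM (SD, n = 2) without dox and at 606 ± 35.6 CPM (SD, n = 2) with dox. The increase was 24.2-fold, or 4.60 ± 0.10 (SE) on the log2 scale, with an adjusted p of 1.43e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the libraries labelled knockout GRHL2 stood at 31.1 ± 1.35 CPM (SD, n = 2), which was not below the no dox level. The difference from no dox was 0.35 ± 0.08 (SE) on the log2 scale, with an adjusted p of 0.00142 by the same edgeR test and Benjamini-Hochberg adjustment. The transcript level therefore does not check the knockout label, a gene-level count cannot show an edit within the transcript, and these 2 libraries are called the libraries labelled knockout throughout.

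The first comparison asked what 7 days of GRHL2 induction changed in the stem cells. Of 25 surface ectoderm genes tested 20 rose and 3 fell, and of 29 pluripotency genes 21 fell and 1 rose. Camera calls of these lists with a preset correlation were lost at adjusted p = 0.214 and 0.383 with an estimated correlation. TFAP2A, a transcription factor of early surface ectoderm, went from 0.117 ± 0.00253 to 12.3 ± 0.713 CPM (SD, n = 2), a rise of 6.66 on the log2 scale. Its no dox level rests on 9 counts over the group, so that SD does not cover counting error and the rise is imprecise. CLDN4, a tight junction claudin, rose from 21.8 ± 0.383 to 139 ± 0.263 CPM (SD, n = 2), 6.31-fold. USP44, a deubiquitinase abundant in pluripotent cells, fell from 217 ± 4.39 to 102 ± 2.79 CPM (SD, n = 2).

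Further genes among the largest rises were EMX2OS (118-fold), MUC15 (80.9-fold), DLX6 (53.3-fold) and HAPLN1 (35.9-fold). EMX2OS and MUC15 had 9.5 and 11 counts over the no dox group, so their folds are imprecise. MUC15 encodes a membrane mucin, DLX6 a homeobox factor and HAPLN1 a link protein of the hyaluronan matrix. EMX2OS is transcribed antisense to EMX2, and the counting is not stated to use strand, so reads of the pair cannot be told apart. Among called genes with a mean of at least 5 CPM and no overlap between the groups, expression fell furthest for CTCFL, LINC00698, NPTX1, EGR3, ERVH48-1 and CXCL5. CTCFL, a germline paralog of CTCF, dropped from 48.2 ± 0.160 to 5.15 ± 0.226 CPM (SD, n = 2), 9.43-fold lower. LINC00698 was 9.36-fold lower, the neuronal pentraxin gene NPTX1 8.08-fold, the immediate early gene EGR3 7.58-fold, ERVH48-1 7.46-fold and the chemokine gene CXCL5 6.49-fold.

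Of 44 epithelial junction and adhesion genes tested, 23 rose, 7 fell and 14 were not called (25 and 7 adjusted over the list alone). CLDN4 was among those that rose, and CGN, which encodes the junction protein cingulin, rose from 53.3 ± 0.106 to 214 ± 8.31 CPM (SD, n = 2). MYO5B, a motor of apical trafficking, rose 3.81-fold. Among 23 epithelial regulators 15 rose and 2 fell (15 and 2 adjusted over the list alone). GRHL1, a paralog of GRHL2, rose 5.42-fold, ERBB3 2.21-fold and ZNF750, an epidermal transcription factor, 10.9-fold. ELF5 stood at 2.74 ± 0.193 CPM with dox and 0.0439 ± 0.0216 CPM without (SD, n = 2), the latter resting on few counts. The surface ectoderm list had 20 of 25 members higher and 3 lower (20 and 3 adjusted over the list alone), with GATA3 up 22.5-fold, MSX2 20.8-fold and the keratin gene KRT19 2.76-fold. By camera with a preset correlation, Benjamini-Hochberg adjusted p was 0.000503 for junctions, 0.000343 for regulators and 2.36e-07 for surface ectoderm. The calls were lost at adjusted p = 0.214 with an estimated correlation for each of these lists.

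In the pluripotency list 21 of 29 genes fell and 1 rose (23 and 1 adjusted over the list alone). JADE1 fell 1.95-fold. POU5F1, chosen after its values were seen, fell from 447 ± 48.7 to 177 ± 31.6 CPM (SD, n = 2), while SOX2, chosen in the same way, was at 446 ± 2.01 and 416 ± 32.5 CPM and was not called. The camera adjusted p of the pluripotency list was 1.79e-07, and adjusted p = 0.383 with an estimated correlation. BMP response genes were higher in 13 of 19 cases and lower in 1 (14 and 1 adjusted over the list alone), led by DLX5, up 35.2-fold to 107 ± 7.87 CPM (SD, n = 2). Its camera adjusted p was 4.06e-05, and adjusted p = 0.214 with an estimated correlation. Amnion and trophoblast genes gave 13 rises and 5 falls among 19 (13 and 5 adjusted over the list alone), with IGFBP3 3.64-fold lower. Genes of craniofacial development and clefting gave 16 rises and 6 falls among 32 (18 and 6 adjusted over the list alone), TFAP2A among the rises. Both lists had a camera adjusted p of 0.0044, and adjusted p = 0.219 with an estimated correlation. GATA3 belongs to the surface ectoderm and amnion lists and TFAP2A to the surface ectoderm and craniofacial lists, so these counts are not independent.

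The remaining lists went both ways and were not called by camera. Neural ectoderm genes rose in 14 and fell in 9 of 29 cases, with the same counts adjusted over the list alone, and PAX6 was 5.11-fold and LHX2 3.41-fold higher. In the neural crest list 8 of 18 rose and 5 fell (9 and 6 adjusted over the list alone), with PAX3 up 13.8-fold and NR2F2 up 7.91-fold. Among mesenchymal genes 8 of 26 rose and 10 fell (9 and 11 adjusted over the list alone), and COL1A1 was 2.70-fold and THY1 2.91-fold lower. Keratinocyte genes rose in 4 and fell in 1 of 8 cases, including TGM1 at 3.07-fold and SFN at 2.09-fold higher. Of 12 mesoderm genes 2 rose and 2 fell, with FOXC1 16.2-fold higher and KDR 3.14-fold lower, and of 10 endoderm genes 2 rose and 3 fell, with LGALS3 2.64-fold higher and APOA1 4.49-fold lower. Retinoic acid response genes rose and fell in 6 cases each of 15, with MEIS1 12.9-fold and MEIS2 5.40-fold higher. The keratinocyte, mesoderm, endoderm and retinoic acid counts were the same adjusted over the list alone. In the integrated stress response list 4 of 28 rose and 10 fell (5 and 10 adjusted over the list alone), with VLDLR 2.47-fold and MTHFD2 1.48-fold lower. Proliferation genes rose in 9 and fell in 8 of 30 cases, with PCNA 1.44-fold and MCM5 1.36-fold lower, and p53 response genes rose in 3 and fell in 8 of 20, with RRM2B 1.67-fold lower and GADD45A 1.92-fold higher. Adjusting the proliferation and p53 lists over the list alone left these counts as they were. For mesoderm the median log2 change was −0.18 and the mean 0.38, and for proliferation 0.05 and −0.02, so their direction depended on the summary. Camera took mesoderm as lower and proliferation as higher, and fry took the opposite sign for each. No gene of the mitochondrial list was in the table.

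Over all genes 18034 were tested and 8296 changed, 4177 higher and 4119 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. At least 2-fold changes numbered 861 higher and 870 lower. The highest adjusted p among the genes named by rule for this comparison was 3.07e-04, for APOA1, in the same edgeR test with Benjamini-Hochberg adjustment. Without no dox replicate 2 fewer genes were called, in a fit whose spread came from the dox pair alone. In simulated counts with far fewer changed genes than were called here, 17.2% of the calls in this design were genes simulated as unchanged. Such a share depends on how many genes change, so it cannot be carried over to the 8296 calls. How many of them are false was not measured. No cells given dox without the GRHL2 construct were analysed here, so effects of GRHL2 and of dox itself cannot be separated.

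**Figure D1:**
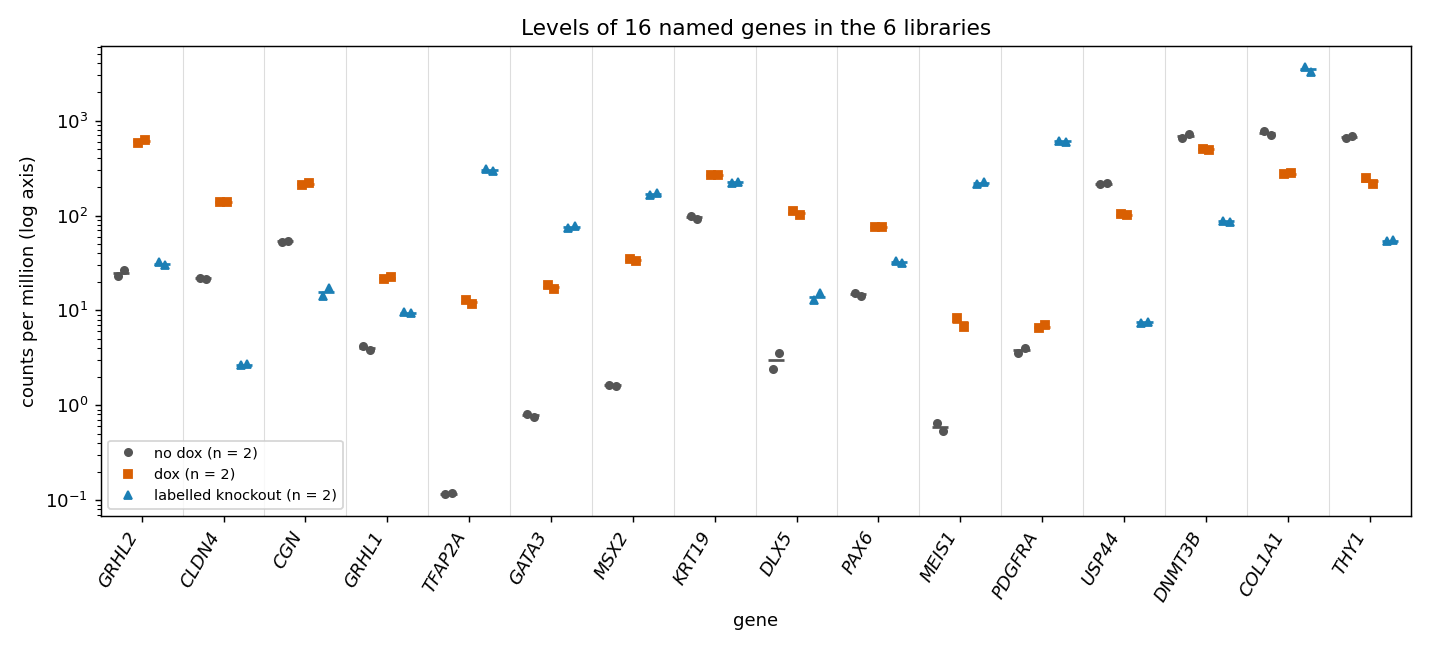
CPM (log axis) of 16 named genes in each of the 6 libraries, with 1 point per library and a short line at each group's mean. TFAP2A lies near 0.117 CPM without dox, near 12.3 CPM with dox and near 303 CPM in the libraries labelled knockout, whereas CLDN4 lies highest with dox, at 139 CPM.

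The second comparison set the libraries labelled knockout beside the no dox libraries. Of 20 BMP response genes tested 18 were higher in them and 0 lower, and of 29 pluripotency genes 25 were lower and 2 higher. Camera calls of these lists with a preset correlation were lost at adjusted p = 0.0673 and 0.186 with an estimated correlation. TFAP2A stood at 303 ± 11.2 CPM (SD, n = 2) against 0.117 ± 0.00253, and HAND2, a heart and limb transcription factor, at 152 ± 2.80 CPM against 0, at least 3916-fold higher when 3 counts over the group are taken as the floor. CDH1, which encodes E-cadherin and was chosen after its values were seen, stood at 17.96 ± 0.907 CPM against 288 ± 13.8 (SD, n = 2). Genotype label, treatment and deposited table differ together here, and no unedited cells given retinoic acid and BMP4 were analysed here, so no difference can be assigned to GRHL2.

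The largest rises besides HAND2 were H19, HOXB3, MIR675 and DCN. H19, an imprinted noncoding RNA, was at 5001 ± 17.5 CPM against 0.0321 ± 0.00482 (SD, n = 2), and MIR675 lies within H19 and shares its reads. HOXB3 was at least 5984-fold higher, MIR675 at least 4714-fold and the proteoglycan gene DCN at least 3899-fold. Among the largest falls, SLC25A6, ASMTL, CD99 and AKAP17A were all at 0 in the libraries labelled knockout. These 4 genes lie in the pseudoautosomal part of chromosome X, which has a copy on chromosome Y, and all 21 pseudoautosomal genes tested had fewer than 10 counts there. TDGF1, the remaining gene and a pluripotency marker with near-identical pseudogenes, was also at 0 against 324 ± 48.5 CPM (SD, n = 2), at least 5611-fold lower, and is uncertain for that reason.

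Among junction and adhesion genes 27 of 44 were lower and 12 higher, with AP1M2, a subunit of an epithelial sorting adaptor, 13.9-fold lower and the desmosomal cadherin gene DSC2 6.20-fold higher. The regulator list had 15 of 23 lower and 3 higher, including the splicing factor gene ESRP1 at 5.63-fold and SPINT1 at 3.73-fold lower. Camera gave Benjamini-Hochberg adjusted p of 0.00854 and 0.0049, and adjusted p = 0.134 and 0.119 with an estimated correlation. Pluripotency genes were lower in 25 of 29 cases and higher in 2, with USP44 28.4-fold and the DNA methyltransferase gene DNMT3B 7.76-fold lower (camera adjusted p = 8.87e-08, and adjusted p = 0.186 with an estimated correlation). The p53 response list had 16 of 20 lower and 2 higher, with CDKN1A 25.9-fold and EDA2R 7.68-fold lower (camera adjusted p = 0.000657, and adjusted p = 0.107 with an estimated correlation).

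Surface ectoderm genes were higher in 19 of 28 cases and lower in 6 (camera adjusted p = 0.000657, and adjusted p = 0.107 with an estimated correlation), and TBX2 was at 196 ± 1.18 CPM against 0.0262 ± 0.00355 (SD, n = 2). Of 20 BMP response genes 18 were higher and 0 lower, with MSX1 462-fold and MSX2 105-fold higher. The retinoic acid list had 20 of 24 higher and 3 lower, with MEIS1 388-fold and MEIS2 78.5-fold higher. In the mesenchymal list 26 of 30 were higher and 3 lower, with POSTN 735-fold and PDGFRA 161-fold higher. Camera adjusted p was 7.68e-07, 8.14e-07 and 1.43e-06 for these lists, and adjusted p = 0.0673 with an estimated correlation for each. Mesoderm genes were higher in 14 and lower in 5 of 19 cases (camera adjusted p = 0.0064, and adjusted p = 0.186 with an estimated correlation). In the dox comparison 12 mesoderm genes and 15 of the retinoic acid list had passed the filter on low counts. Likewise 26 mesenchymal, 25 surface ectoderm, 18 neural crest and 19 BMP response genes had passed it there. The further genes tested here passed it with the libraries labelled knockout in the model, which favours higher values in those libraries. GATA4 stood at 219 ± 3.19 CPM and GATA6 at 208 ± 0.629 CPM (SD, n = 2), against 0.189 ± 0.0845 and 0.0499 ± 0.0299 CPM. Neural crest genes were higher in 13 and lower in 5 of 20 cases, with NR2F2 186-fold and TWIST1 2060-fold higher (camera adjusted p = 0.039, and adjusted p = 0.28 with an estimated correlation). That call was lost without replicate B of the libraries labelled knockout, where camera adjusted p was 0.0542.

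Lists not called by camera were endoderm (10 higher and 5 lower of 15), amnion and trophoblast (10 and 4 of 19), keratinocyte (2 and 4 of 8), craniofacial (18 and 11 of 33), integrated stress response (13 and 7 of 28), proliferation (13 and 12 of 30) and neural ectoderm (15 and 15 of 32). Endoderm was called without no dox replicate 1 or 2, at camera adjusted p of 0.0336 and 0.0444 against 0.0607 with all libraries, and amnion and trophoblast without no dox replicate 1, at 0.0457 against 0.0526. With an estimated correlation these became adjusted p = 0.364 and 0.42 for endoderm and 0.364 for amnion and trophoblast. Within the lists not called HEY1 was 12.5-fold, GATA3 98.4-fold, DSC3 11.9-fold, SLC7A5 3.33-fold, MCM2 2.59-fold, RRM2 2.36-fold and DCX 89.2-fold higher. SFN was 49.8-fold, GDF15 23.6-fold and OTX2 122-fold lower. For neural ectoderm the median log2 difference was −0.37 and the mean −0.11, while fry gave the opposite direction. In this comparison the counts of each list were the same adjusted over the list alone.

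Altogether 14751 of 18822 genes tested differed, 7306 higher and 7445 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. At least 2-fold differences numbered 3502 higher and 3562 lower.

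**Figure D2:**
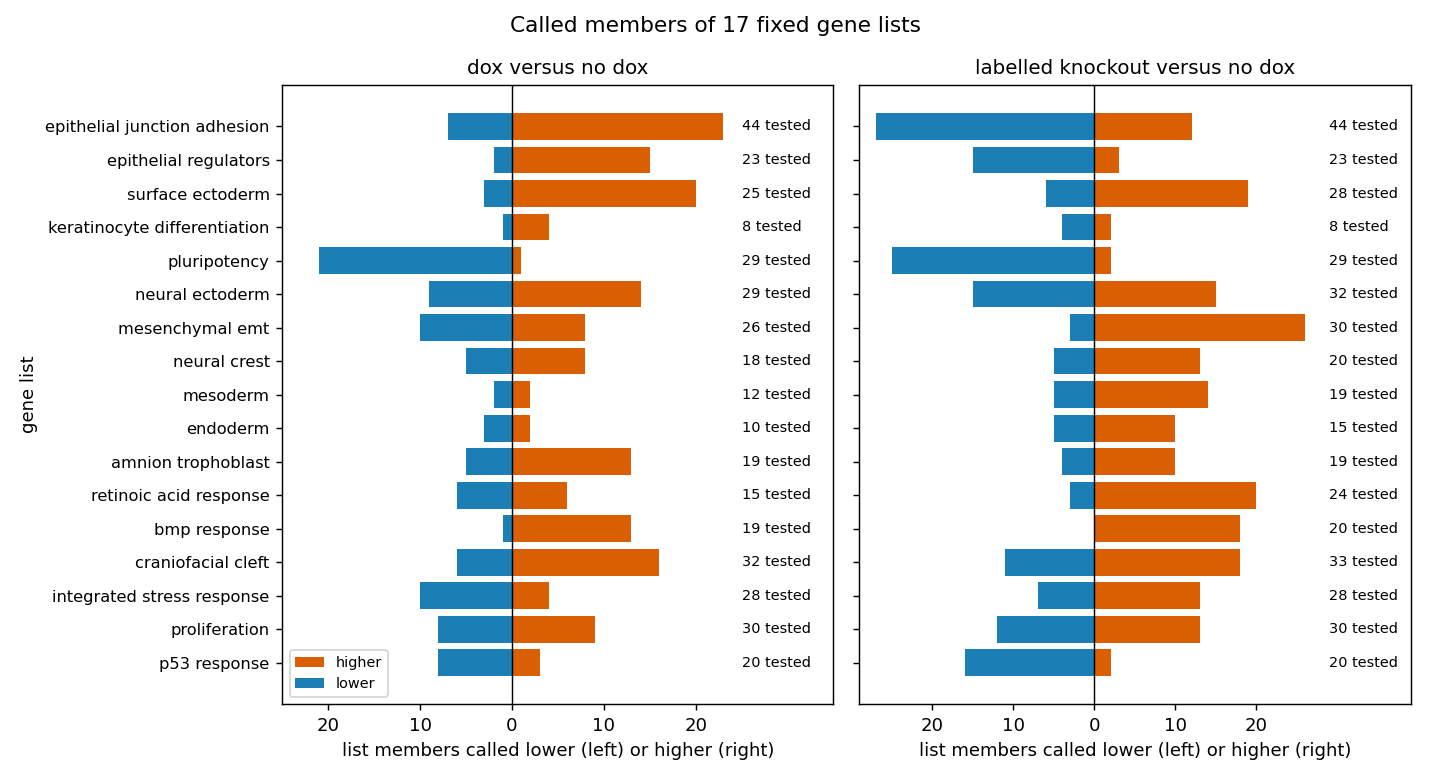
Number of members of 17 gene lists called higher (right, orange) or lower (left, blue) in dox against no dox (left panel) and in the libraries labelled knockout against no dox (right panel), with the number tested at the right of each bar. In the junction list 23 of 44 genes were higher with dox, and 27 of 44 were lower in the libraries labelled knockout.

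The third comparison set the libraries labelled knockout beside the dox libraries, with the same differences of treatment and table. Junction and adhesion genes were lower in 32 of 44 cases and higher in 11, and CLDN4 was 50.2-fold and AP1M2 14.3-fold lower. Epithelial regulators were lower in 19 of 23 cases and higher in 3, including ESRP1 at 5.02-fold and the serine protease gene PRSS8 at 4.43-fold lower. Camera adjusted p was 0.00024 and 7.46e-05, and adjusted p = 0.0824 and 0.0779 with an estimated correlation. GRHL2 itself was 19.0-fold lower.

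Pluripotency genes were again lower in 25 of 29 cases and higher in 2, with USP44 13.3-fold and DNMT3B 5.58-fold lower (camera adjusted p = 6.80e-07, and adjusted p = 0.229 with an estimated correlation). The p53 list had 16 of 20 lower and 2 higher, with CDKN1A 25.1-fold and EDA2R 7.67-fold lower (camera adjusted p = 0.000636, and adjusted p = 0.0912 with an estimated correlation). Mesenchymal genes were higher in 24 and lower in 3 of 30 cases, with POSTN 847-fold and TGFB2 114-fold higher. The retinoic acid list had 19 of 24 higher and 3 lower, with TSHZ1 95.9-fold higher and HOXB3 at 233 ± 9.81 CPM against 0.0137 ± 0.0194 (SD, n = 2). BMP response genes were higher in 17 and lower in 3 of 20 cases, with MSX1 339-fold and TBX3 89.8-fold higher. Camera adjusted p was 6.80e-07 for the mesenchymal and retinoic acid lists and 6.39e-05 for BMP, and adjusted p = 0.0779 with an estimated correlation for each. Mesoderm genes were higher in 14 and lower in 5 of 19 cases (camera adjusted p = 0.0048, and adjusted p = 0.229 with an estimated correlation). Endoderm genes were higher in 10 and lower in 5 of 15 cases (camera adjusted p = 0.0478, and adjusted p = 0.336 with an estimated correlation). In the dox comparison 10 endoderm genes had passed the filter on low counts. Further members of this and several other lists passed it through the libraries labelled knockout, which favours higher values there. GATA4 and GATA6 belong to the mesoderm and endoderm lists, so these counts are not independent. The endoderm call was lost without any 1 of the 4 libraries compared, with camera adjusted p between 0.0567 and 0.0739.

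Not called by camera were surface ectoderm (16 higher and 11 lower of 28), neural crest (11 and 7 of 20), neural ectoderm (12 and 17 of 32), amnion and trophoblast (11 and 7 of 19), keratinocyte (2 and 4 of 8), craniofacial (17 and 13 of 33), integrated stress response (13 and 6 of 28) and proliferation (15 and 13 of 30). Only neural crest (11 and 8) and neural ectoderm (12 and 18) had other counts adjusted over the list alone. Among their members TFAP2C was 14.8-fold, SFN 104-fold, GDF15 16.2-fold and OTX2 172-fold lower. NR2F2 was 23.5-fold, TWIST1 637-fold, PDGFRA 92.0-fold, DCX 173-fold, HEY1 8.66-fold, SLC7A5 2.67-fold, MCM2 3.32-fold and RRM2 2.60-fold higher, and DSC3 was higher by 3.47 on the log2 scale. TBX2 was at 196 ± 1.18 CPM against 0.0416 ± 0.000635, and GATA4 and GATA6 were at 0.0623 ± 0.00884 CPM each in dox (SD, n = 2). Median and mean log2 differences had opposite signs for amnion and trophoblast, at 1.02 and −0.45, and fry gave neural ectoderm as higher against a median of −0.95 and a mean of −0.65. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, 14597 genes differed, 7142 higher and 7455 lower, of which 3190 and 3629 differed at least 2-fold.

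Genes changed by dox were then compared with genes that differed in the libraries labelled knockout, both against the same no dox libraries and in 1 model of 3 groups. Higher in both were 2375 genes, and lower in both 2709, where independent lists would share 1715 and 1723. Higher with dox and lower in the libraries labelled knockout were 1266 genes, and the reverse held for 931. In 20 simulations of unchanged groups against these controls, a mean of 1.95 called genes were shared in the same direction, and at most 4. When as many genes were taken from each simulated ranking as had been called, 2711 higher and 2669 lower genes were shared. Those rankings hold no effects, unlike the real calls, so the observed overlap cannot be judged against these values. With a 2-fold minimum as well, 442 genes were higher in both and 568 lower in both, where independent lists would share 169 and 168. In opposite directions 157 and 133 were shared, where independent lists would share 171 and 165. The controls cannot be split into groups of 2 libraries each, so how much of the excess over independent lists comes from them stays open.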

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

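Among the alternatives, protein-coding genes alone, thinned libraries, omission of pseudoautosomal and identical-copy genes, and midway values rounded down were chosen after seeing the data. Genes named by the rule kept their direction and their side of the threshold in all 1700 values recomputed under the alternatives. Apart from GRHL2 they had been picked for large changes or small adjusted p in these same libraries, so this says little about other called genes. Counts of changed genes moved by over 1.5 times in these cases. Requiring a 2-fold change left 1731 genes for dox against no dox, 7064 for the libraries labelled knockout against no dox and 6819 against dox, by construction, and 1010 shared in the same direction where 5084 had been. Leaving out each library in turn gave 5524 to 8911 genes for dox, where 8296 were called with all, and the lowest value came without no dox replicate 2. Each of these fits has a lone library assumed to vary like the other group, whose pair alone gives the spread. All of them hold the same number of libraries. The count was above that with all libraries when a dox library was left out, and below it when a no dox library was. Fewer libraries alone therefore do not explain the drop, which came where the dox pair gave the spread. With all libraries thinned to the smallest, that pair differed by a chi-square per degree of freedom of 10.9, against 3.90 in no dox. Whether this moved the count was not tested. DESeq2 called 6115 genes for dox and limma voom 8285. With an estimated correlation camera called 0 of 17 lists in each comparison, where the preset one called 7, 10 and 9. The lowest adjusted p of camera were then 0.214, 0.0673 and 0.0779. That setting also rests on the few residual degrees of freedom of each fit, so the loss does not measure correlation alone. Fry, which does not set a list against other genes, called 12, 17 and 17, but called no list for dox without no dox replicate 1 or 2 (lowest adjusted p 0.0833 and 0.0592), and 8 or 9 without a dox library. In each of these fits the spread comes from the remaining pair, with 1 residual degree of freedom. That number is the same without a dox library, so it alone does not explain the loss. The fry calls for dox depended on which group kept both libraries. With the replicate number as a block, 7320 genes and 7 lists were called for dox. Same-numbered deviations correlated at −0.0601 across genes, so no common shift by replicate number was seen. Whether same-numbered dox and no dox cultures shared a preparation is not known here. No paired analysis was possible because the columns of the libraries labelled knockout carry letters and not replicate numbers, for either comparison that uses them. Summing rows of a gene was not run, as each symbol has 1 row. Thinning every library to the smallest left 8124 genes for dox, 14282 for the libraries labelled knockout against no dox and 14086 against dox. In simulated counts 44.5% of genes changed by 0.5 on the log2 scale were recovered for dox, at the depth and number of libraries in hand.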

Other observations

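The gene lists of this part, HOX genes included, and the tests of discarded reads and identical copies, of replicates at equal depth, of GRHL2's own level and of unedited cells were chosen after the results were seen. Targets of growth factor and ERK signalling, taken from textbook knowledge after EGR3, EGR2 and FOS had been seen to fall, were lower in 16 of 24 cases with dox and higher in 1. PHLDA1 went from 334 ± 9.29 to 84.5 ± 1.55 CPM, EGR1 from 210 ± 13.3 to 58.4 ± 7.41 CPM and FOS from 75.7 ± 16.2 to 16.8 ± 1.36 CPM (SD, n = 2). Not called were 7 genes, among them DUSP4, SPRY1 and SPRED1, and the 1 that rose was SPRED2, by 0.39 on the log2 scale. Without EGR3, EGR2 and FOS 13 of 21 fell and 1 rose, with a camera p of 0.000545, unadjusted, and p = 0.203 with an estimated correlation. Genes of the neural plate border and placodes rose in 14 of 19 cases with dox and fell in 2, including PAX7 (11.2 ± 1.97 to 61.5 ± 3.53 CPM) and SP8 (10.5 ± 0.00432 to 62.0 ± 0.150 CPM; SD, n = 2). ZIC1, of the same list, fell from 3.39 ± 0.201 to 0.388 ± 0.00593 CPM. The list was drawn up after PAX3, PAX7, SP8, DLX5, DLX6 and others of its members had been seen to rise, so its count is no test of the group. Without members seen beforehand, FOXC1 and EMX2, whose reads cannot be told apart from those of EMX2OS, 6 of 11 rose and 2 fell, and the group was not called, with a camera p of 0.217, unadjusted, and p = 0.325 with an estimated correlation.

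HOX genes set the libraries labelled knockout apart from the dox and no dox libraries. Of 39 HOX genes, 18 reached 1 CPM in each library labelled knockout, with totals of 1204 and 1186 CPM, and 0 did so in any of the other 4 libraries, whose totals were 0.0574 to 0.882 CPM. In the comparison with no dox 21 of 22 HOX genes tested were higher. In the dox comparison 1 HOX gene had passed the filter on low counts. The others passed it through the libraries labelled knockout, so this count was largely set by the filter and is no test. HOXB3 had been seen among the largest rises there before the HOX genes were counted, and some HOX genes are also in the retinoic acid list.

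Pseudoautosomal genes were nearly empty in the libraries labelled knockout: 21 genes held 110609.5 counts without dox, 106619 with dox and 9 in those libraries. Loss of the ends of the X chromosome that reaches beyond these regions is argued against. Of 88 neighbouring genes within 5 Mb with 10 or more counts without dox, 87.5% also had them there. Beside the region at the chromosome's start 10 of 11 did so, and beside the other region 67 of 77. Genes outside the regions cannot show a loss confined to them. That reads matching the X and Y copies alike may have been discarded when that table was made stays open, because the median log2 difference of the neighbours, −0.195, would be near 0 under other accounts too. Of 89 genes outside these regions with a transcript identical to another gene's and 10 or more counts without dox, 75 kept 10 or more in the libraries labelled knockout. A gene entered this count when any of its transcripts was identical, so its other transcripts can supply reads. The count therefore cannot show whether reads with several matches were kept there. Of the 36 genes at 0 there with 1000 or more counts in the other table's libraries, 12 were pseudoautosomal, 10 were copies of ribosomal or 7SL RNA and 14 were neither, and 0 of the 12 among the latter with a known sequence had an identical transcript elsewhere.

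GRHL2 was not reduced in the libraries labelled knockout relative to no dox. An exchange with the dox libraries was tested in a pair of ways. The planned test, the median log2 difference from dox of genes raised at least 4-fold by dox, gave −1.19 with an interquartile range of 5.28 and did not decide it, whereas GRHL2's own difference of −4.25 argues against it. That an edited allele still makes a transcript may hold, and 1598 counts without reads per exon leave it open. Unedited cells given retinoic acid and BMP4 could also stand under the label, and the median difference of −1.23 for junction genes cannot decide this without such cells to compare.

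With all libraries thinned to the smallest, the dox libraries differed from each other with a chi-square per degree of freedom of 10.9, against 3.90 in no dox and 2.86 in the libraries labelled knockout, and the median absolute log2 ratio of genes with a mean of at least 5 CPM was 0.0865, against 0.0675 and 0.065. A batch shared by replicate number is argued against by a correlation of −0.0601 between the dox and no dox replicate ratios. GC content and length had an R squared of 0.0636 for the dox 2 to dox 1 log ratio. The correlation of that ratio with the dox effect was 0.148 before and 0.149 after removing their trend. This argues against a GC or length bias as the source of that correlation. The correlation is weak and is not the spread between the dox libraries, so the test does not settle what caused the spread. Whether replicate 2 may have responded more strongly stays open. Its slope on replicate 1 was 0.950 or 0.983 and, under the prediction written beforehand, a value below 1 would have counted against it, but the reverse slope of 0.922 was also below 1, as noise in the predictor brings, so that prediction was wrong.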
